A study of Caenorhabditis elegans with 2 samples.

How the data were processed

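Chromatin of embryos expressing MLS-2 with a C-terminal GFP-FLAG tag was sheared by sonication and precipitated with an anti-GFP antibody, per the labels, in 2 biological replicates of 1 group. The labels name them as separate biological replicates, and they name a possible control experiment that was not analysed here. The deposited files were peak lists in narrowPeak format for ce10 and ce11. For each build there were 2 replicate lists and a pooled list, which the deposited file descriptions call peaks and background used as input for the irreproducible discovery rate (IDR), with 30000 regions each. A list of optimal IDR-thresholded peaks held 1925 peaks in ce11 and 1926 in ce10. Per the deposited file descriptions, the lists were made from the replicate alignments together with a control alignment. The peak caller, the aligner, the IDR threshold and all versions are not given in the sources used here.

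Each deposited list gives a signal value per peak, the authors' peak score, whose scaling is not stated. Signals differ in range between lists, with a maximum of 1669 in replicate 1, 1245 in replicate 2 and 2651 in the pooled list, so they were used to rank peaks within a list and, between replicates, in a rank correlation and a correlation of log2 values across peaks. The −log10 q per peak in the deposited lists reached its maximum in 1772 of the 1925 peaks and was not used for ranking. A check of the files showed that the optimal list is the same as the 1925 pooled regions of highest signal, with a lowest signal of 212. Of the optimal peaks, 1372 had a width of 470 bp. Read totals were not in the files used here, so the depth per sample is unknown, and no precision could be derived from it. Intervals on shares cover counting error only and treat peaks or genes as independent, although 196 summits lay within 250 bp of another.

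Peaks were annotated with the WBcel235 genome, which is ce11, and its Ensembl gene annotation (19973 protein-coding genes on nuclear chromosomes). The ce10 lists were used only as alternatives for the peak count, the X share and the replicate measures, and no coordinates were converted between builds. A gene's promoter window ran from 1000 bp upstream to 100 bp downstream of the 5′ end of each protein-coding transcript. Small RNA genes were those annotated as tRNA, snoRNA, snRNA or miRNA, with a summit within 200 bp. Replicate agreement required a summit within 100 bp among the strongest regions of the replicate's list, as many as there were optimal peaks, and was set against 100 random circular shifts. Shares of summits in a class were set against 1000 random placements within chromosomes (permutation test, one-sided), and the X share against the exact binomial distribution.

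Before the data were examined, 23 gene lists, their tests, the motif panel and the rule for naming genes were fixed. Gene lists were tested with Fisher's exact test (two-sided) against all other protein-coding genes with Benjamini-Hochberg adjustment, and against 10000 random lists matched on the decile of upstream intergenic length. Of the list members, 4 symbols matched no protein-coding gene (exc-2, lsy-6, nca-1 and ram-4) and were left out. The 9 motifs were sought on both strands within 50 bp of the summit and in a 101-bp window centred 350 bp away, with an exact McNemar test. The plan set that side with a fixed seed, and the analysis set it by a fixed pseudo-random rule on the summit position, so that a peak kept its side in every list. Text names the nearest gene to the 20 strongest peaks, every gene of the list tied to mls-2, the 4 members with the highest promoter signal in each list that passed, and mls-2 and unc-119. Small RNA genes and genes in the closing observations were named after their values were seen.

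Alternatives chosen before the files were opened were a stricter list (the 962 strongest peaks), the list of each replicate alone in place of the pooled list, the ce10 lists, upstream windows of 500 and 2000 bp, assignment to the nearest gene within 5000 bp, motif windows of 25 and 100 bp, the motif core CAATTA, promoters of genes without a peak as controls, 3 groups in place of 5 by signal, and 50 kb around the loci. Alternatives added after the data were seen were leaving out summits near small RNA genes, leaving out mitochondrial regions, 10 control positions per peak with the same G and C count on the same chromosome, within 1 base and more than 500 bp from any summit (also outside exons), and nearest-gene lists matched on the length of genome nearest to each gene. On simulated data, 1925 random summits gave 0 calls among the lists and 0 among the motifs, including with the matched lists and the controls of the same G and C count. All of 200 genes given a summit (100%) were recovered. A homeobox list with summits at 51 of 102 genes and CAATTAA written at 642 of 1925 summits were both called. The random summits were placed uniformly within chromosomes, without the G and C content or promoter share of the real ones. The 0 calls therefore do not cover those biases. The planted shares were also larger than those observed in the lists and motifs, so power at the observed sizes is not shown. Computations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.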

Results

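The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for MLS-2, a homeodomain protein of the HMX/NKX5 family that acts in mesoderm, glia and neurons of the nematode Caenorhabditis elegans. The worms were of strain OP645, which carries an integrated transgene (wgIs645) encoding MLS-2 with a C-terminal GFP-FLAG tag in an unc-119(tm4063) background. Whole mixed-stage embryos were taken 2 h after synchronization by egg bleaching, and the tagged protein was precipitated with an anti-GFP antibody. The series held 1 group of 2 biological replicates, so that no comparison between conditions was possible. The questions the design allows are where MLS-2 was found, how well both replicates placed it, and which genes and sequences lay at the peaks. Read totals per sample were not given in the sources used here, so the depth is unknown. All coordinates are in ce11 (WBcel235), 1-based, and all signal values are the authors' own peak scores, used to rank peaks within a list. Each p-value describes the pooled peak list, or the list of 1 replicate where that is named, and counts peaks or genes, not animals.

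The authors' thresholded list held 1925 peaks, 24.0 per Mb on chromosome I, 10.8 per Mb on chromosome V and 27.4 per Mb on chromosome X. The 20 strongest peaks lay mostly beside small structural RNA genes, with 10 within 200 bp of a small nucleolar RNA (snoRNA), small nuclear RNA (snRNA) or microRNA (miRNA) gene and 2 within 200 bp of a tRNA gene. The first was at V 12303366–12303891, with a signal of 2651, in an intron of a protein-coding gene and beside the snoRNA genes C51F7.3 and C51F7.4. The second was at II 11960607–11961122, with a signal of 2377, beside the snoRNA gene W03C9.9. Peaks 5 and 16 lay beside the miRNA genes mir-51 (IV 11025811–11026486, signal 1970) and mir-52 (IV 14033413–14034486, signal 1349). Another 7 of the 20 were in promoter windows, taken from 1000 bp upstream to 100 bp downstream of the 5′ end of a protein-coding transcript. These belonged to K12H4.5 (III 8043752–8044196, signal 2014), to atx-2, the ataxin-2 gene (III 10461095–10461525, signal 1647, summit 63 bp upstream of the 5′ end), and to ftt-2, which encodes a 14-3-3 protein (X 11605580–11606478, signal 1538). The others were at idhg-1, a subunit of mitochondrial isocitrate dehydrogenase (III 4568570–4568926, signal 1423), rpl-3, a ribosomal protein gene (III 3867412–3867764, signal 1385), ears-2, a mitochondrial glutamyl-tRNA synthetase (IV 390316–390684, signal 1289), and tasp-1 (III 10759052–10759444, signal 1215). The remaining nearest genes were F55C5.17, W03C9.1, cutl-18, hrg-5, sre-23, str-56, C04A11.5, pxn-1, T02E1.2, Y43F8C.7, Y37A1B.7, nas-30 and ets-5. Of these, sre-23 and T02E1.2 had the summit in their own promoter window, 626 bp and 462 bp upstream of the 5′ end. The summit lay at -4965 bp from the 5′ end of nas-30, an astacin protease gene, with no small RNA gene within 200 bp.

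Both replicates placed most of these peaks. Each of the 20 strongest peaks ranked 21 or better in replicate 1 and 41 or better in replicate 2. Of the 1925 peaks, 1221 (63.4%, 95% exact binomial interval 61.2 to 65.6) had a summit within 100 bp in the 1925 strongest regions of each replicate's own list. Replicate 1 held 1667 of them (86.6%), replicate 2 held 1413 (73.4%), and 66 were found in neither. After 100 random circular shifts of the replicate lists, a mean of 0.0042% and at most 0.052% of peaks were found in both. The peaks were chosen from the same 2 replicates pooled, so an excess over the shifts was largely built in. Compared directly, 1213 of the 1925 strongest regions of replicate 1 (63.0%) had a summit within 100 bp among those of replicate 2. Against all 30000 regions of each replicate's list, 1810 peaks (94.0%) were found in both. Across those 1810 peaks the replicates' signals had a Spearman rho of 0.67 (95% bootstrap interval 0.64 to 0.70) and a Pearson r of 0.80 on the log2 scale. These are correlations across peaks of a list chosen on the same data, and peaks are not independent replicates. The share found in both moved with the rule, to 51% at 50 bp and 70.2% for any overlap of the intervals.

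Peaks were concentrated on the X chromosome and sparse on chromosomes IV and V. The X chromosome held 486 of 1925 peaks (25%, 95% exact binomial interval 23.3 to 27.3), against 17.7% of the nuclear genome. That is 1.43 times the share expected from its length (exact binomial test, two-sided, p = 9.4e-17). Chromosome IV held 12.9% of the peaks and 17.4% of the genome, and chromosome V held 11.7% and 20.9%. Of 612 nuclear tRNA genes, 276 lie on X, and without the summits near tRNA genes the X ratio was 1.32. Without those near snoRNA, snRNA and miRNA genes as well it was 1.39, both choices made after the data were seen.

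**Figure D1:**
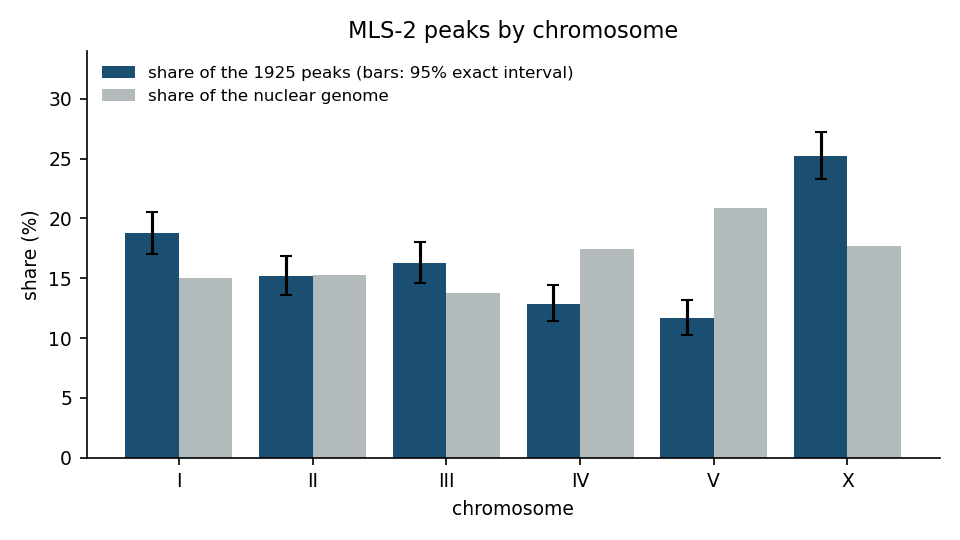
Share of the 1925 peaks on each chromosome (dark bars, %, with 95% exact binomial intervals) beside the chromosome's share of the nuclear genome (grey bars, %). X holds 25% of the peaks and 17.7% of the genome, and V holds 11.7% and 20.9%.

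Peaks sat at tRNA and other small RNA genes and at promoters, and were rare in exons. Summits within 200 bp of a tRNA gene numbered 191 (9.92%, 95% exact binomial interval 8.62 to 11.3), against 0.311% of random placements within the same chromosomes. That is a 31.9-fold excess (permutation test over 1000 placements, one-sided, p = 0.001, the smallest they can give). The excess was 32.2-fold in the list of replicate 1 and 34.9-fold in that of replicate 2. Of the tRNA genes, 198 of 612 (32.4%) had a summit within 200 bp. A summit was found at 168 of 469 tRNA genes that have an identical copy elsewhere (35.8%) and at 30 of 143 with a unique sequence (21%), and reads of identical copies cannot be told apart. No control library was analysed here, so an excess at small RNA genes that does not depend on MLS-2 was not excluded. Near snoRNA genes there were 70 summits (19.9-fold), near snRNA genes 15 (13.7-fold) and near miRNA genes 14 (5.91-fold), each with a permutation p of 0.001. Among the 20 annotated rRNA genes none had a summit within 200 bp. Near genes annotated as other noncoding RNA there were 500 summits (7.05-fold, permutation p = 0.001). Pseudogenes had 11 summits, 0.163 times the random number, and piRNA genes 13, or 0.269 times.

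Promoter windows of protein-coding genes held 913 of 1925 summits (47.4%, 95% exact binomial interval 45.2 to 49.7), against 23.5% of random placements. The excess was 2.02-fold (permutation test over 1000 placements, one-sided, p = 0.001, the smallest they can give). The median summit lay 859 bp from the nearest protein-coding 5′ end, and 1126 of 19973 protein-coding genes (5.64%) had a summit in their window. With each summit counted once, in the order small RNA gene, promoter window, exon, intron and other sequence, exons held 35 summits (1.82%, against 22.7% expected from their length). Introns held 304 (15.8%, against 28.4%), and other intergenic sequence held 462 (24.0%, against 24.9%). Among the 385 strongest peaks, 24.9% of summits were near a tRNA gene and 14.8% near a snoRNA, snRNA or miRNA gene. Among the 385 weakest these shares were 3.90% and 1.56%, and the promoter share was 39.2%, 48.1%, 46.8%, 43.9% and 39% from the strongest to the weakest of 5 groups. Small RNA genes were counted first, which lowers the promoter share most among the strongest peaks.

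**Figure D2:**
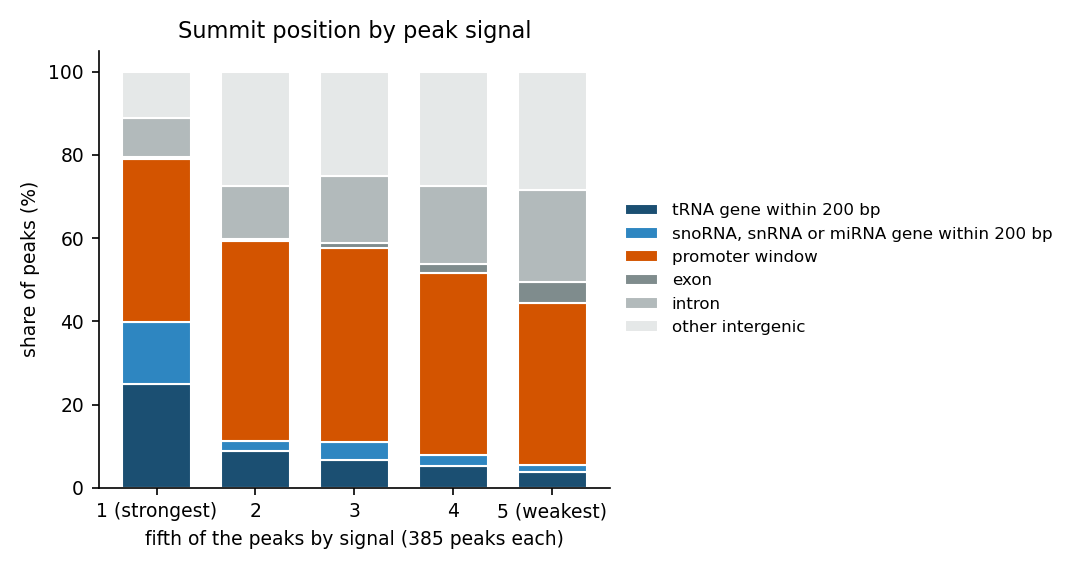
Share of summits (%) in each position class for 5 groups of 385 peaks by signal, from strongest to weakest. The tRNA share goes from 24.9% in the strongest group to 3.90% in the weakest, and the intron share from 9.35% to 22.1%.

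Ribosomal protein and histone genes carried promoter peaks more often than other genes, and chemoreceptor genes carried them less often. Of 23 gene lists fixed before the data were examined, these 3 and the cell cycle list passed Fisher's exact test (two-sided, Benjamini-Hochberg over the 23 lists) and 19 lists did not, the lowest adjusted p of those being 0.27 by the same exact test. Of the lists that passed, ribosomal proteins had been fixed as a housekeeping control and chemoreceptors as a control list. No control library was analysed here, so promoter peaks that do not depend on MLS-2 were not excluded. Among 80 cytosolic ribosomal protein genes, 29 (36.3%, 95% exact binomial interval 25.8 to 47.8) had a promoter summit, against 5.51% of other genes (odds ratio 9.74, Fisher's exact adjusted p = 1.6e-15). The strongest were rpl-3 (signal 1385), rpl-15 (IV 654766–655082, signal 756), rps-28 (IV 1659090–1659408, signal 722) and rps-26 (I 14759353–14759677, signal 656), the last within 200 bp of a small RNA gene. Among 72 histone genes, 13 (18.1%, interval 9.98 to 28.9) had one, with an odds ratio of 3.72 and a Fisher's exact adjusted p of 0.0013. With each peak given to the nearest gene the histone list did not pass (Fisher's exact adjusted p = 0.34, and 0.11 by permutation when matched on stretch length). Neighbouring histone genes shared peaks, so that the 13 genes rested on 9 peaks as each gene's strongest. One peak between his-67 and his-68 (I 9988816–9989149) had a signal of 752, and one between his-61 and his-62 (IV 7486226–7486559) had a signal of 516. Among 30 cell cycle regulators, 6 (20%, interval 7.71 to 38.6) had one (odds ratio 4.20, Fisher's exact adjusted p = 0.034). They included lin-35, the retinoblastoma-family gene (I 5807429–5807646, signal 593), wee-1.3, a CDK-inhibitory kinase gene (II 9716648–9717117, signal 284), cki-1, a CDK inhibitor gene (II 7810930–7811120, signal 273), and cdk-4 (X 13518971–13519440, signal 261). The lin-35 peak also lay in the promoter window of vps-51. The cell cycle result passed narrowly and was lost in several settings. The adjusted p was 0.087 in the permutation test matched on upstream length and, by Fisher's exact test, 0.23 in the list of replicate 2 alone, 0.21 at 500 bp and 0.86 among the 962 strongest peaks.

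Of 1310 chemoreceptor genes, which are expressed mainly in sensory neurons, 7 (0.534%, interval 0.215 to 1.10) had a promoter summit, against 6.0% of other genes (odds ratio 0.084, Fisher's exact adjusted p = 1.9e-23). The 4 with the highest signals were sre-23 (I 8259336–8259765, signal 1903), sre-1 (II 7708629–7708918, signal 856), sri-5 (I 11182396–11182660, signal 526) and srh-269 (V 16592206–16592399, signal 372). The strongest summit of 2 of the 7 genes lay within 200 bp of a small RNA gene, that of sre-23 beside the snoRNA gene ZK265.10. Against 10000 random lists matched on the length of the upstream intergenic region, 3 lists passed: ribosomal proteins (4.71 times the matched expectation) and chemoreceptors (0.091 times), both with a permutation adjusted p of 0.0023, and histones (2.36 times, permutation adjusted p = 0.041).

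**Figure D3:**
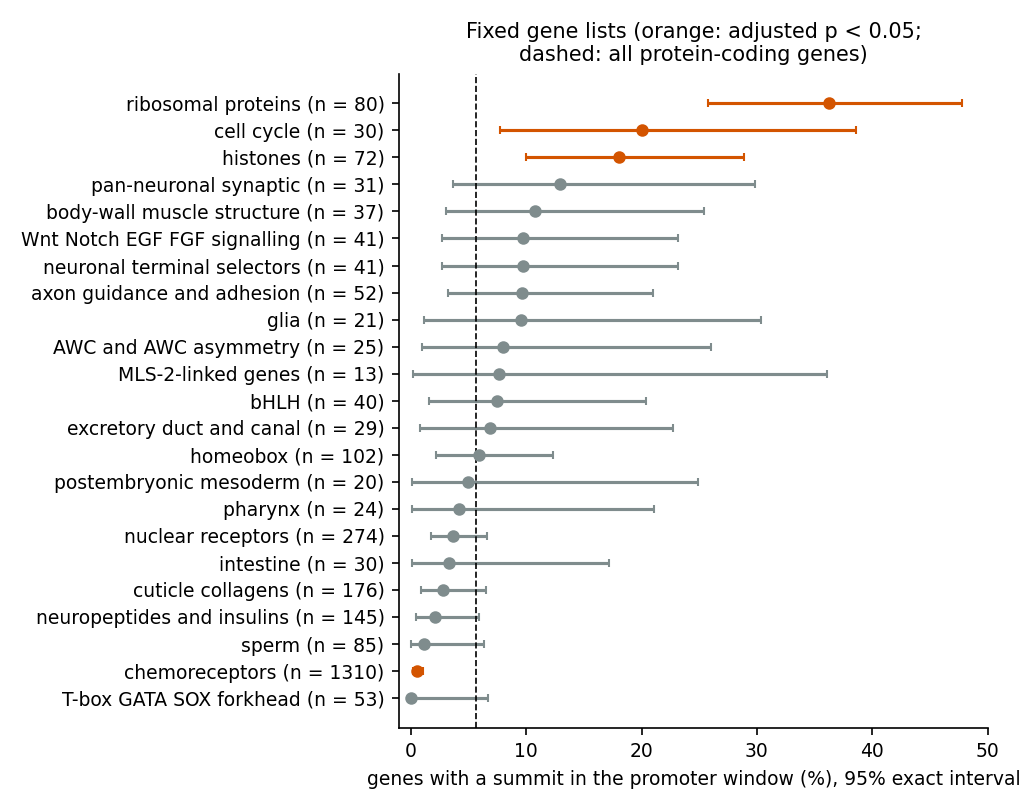
Share of each fixed list's genes with a summit in the promoter window (points, %, with 95% exact binomial intervals). The dashed line marks all protein-coding genes (5.64%), and orange points mark the 4 lists with an adjusted p under 0.05. Ribosomal proteins stand at 36.3% and chemoreceptors at 0.534%.

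Genes tied to mls-2 in earlier genetic work did not pass as a list. Of the 13 genes in that list, only cye-1, the cyclin E gene, had a summit in its promoter window (I 6779994–6780463, signal 239, rank 1504, summit 577 bp upstream). The share of 7.69% (95% exact binomial interval 0.19 to 36) did not differ from that of other genes (Fisher's exact test, adjusted p = 0.72), and with 13 genes the interval reaches from below to far above the 5.64% of all genes. In the list of replicate 2 alone none of the 13 genes had a promoter summit, and in that of replicate 1 alone 1 did. In the pooled list the nearest summits of let-60 (Ras) and vab-3 (Pax6) lay 1344 bp and 2969 bp from a 5′ end. For nsy-1 that distance was 5315 bp and for ceh-36, an AWC neuron homeobox gene, 12553 bp. For hlh-17, hlh-8, hlh-1, fozi-1, lin-48, lin-3, ptr-10 and lim-4 the distances ran from 23628 bp at lin-3 to 127671 bp at hlh-17. Of these, hlh-8, hlh-1 and fozi-1 are also on the list of postembryonic mesoderm, and the material was whole mixed-stage embryos. Binding at later stages or in a few cells was not examined, so a missing peak does not show that MLS-2 never binds there.

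The lists of developmental and neuronal genes did not pass with the promoter window in the pooled list. Pan-neuronal synaptic genes passed in the list of replicate 1 alone and in that of replicate 2 alone (6 of 31 in each, Fisher's exact adjusted p = 0.033 and 0.028). With 2000 bp upstream, pan-neuronal synaptic, axon guidance and signalling pathway genes passed (Fisher's exact adjusted p = 4.9e-04, 0.0096 and 0.044). In the pooled list with 1000 bp, promoter summits were found at 6 of 102 homeobox genes (5.88%), 2 of 21 glial genes, 1 of 20 postembryonic mesoderm genes, 2 of 25 AWC genes, 2 of 29 excretory genes and 3 of 40 basic helix-loop-helix genes. They were found at 4 of 41 neuronal terminal selectors, 4 of 31 pan-neuronal synaptic genes, 5 of 52 axon guidance genes, 4 of 41 Wnt, Notch, EGF and FGF pathway genes and 10 of 274 nuclear receptors. None of 53 T-box, GATA, SOX and forkhead genes had one, which the interval limits to 6.72%, and the Fisher's exact p was 0.074 before adjustment. In the list of replicate 1 alone 2 of the 53 had one, and in that of replicate 2 alone 1 did. The other lists, again with the pooled peaks, were body-wall muscle (4 of 37), cuticle collagens (5 of 176), neuropeptides and insulins (3 of 145), intestine (1 of 30), pharynx (1 of 24) and sperm (1 of 85). When each peak was given to the gene with the nearest 5′ end within 5000 bp instead, 11 of the 23 lists passed, 8 of them lists of developmental or neuronal genes that did not pass with 1000 bp in the pooled list.

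CAATTAA, fixed beforehand as the motif for the HMX family, was rare at the summits, and its direction depended on the control. It occurred within 50 bp of 33 of 1925 summits (1.71%) and in 59 of the flanking windows centred 350 bp away (3.06%), a ratio of 0.56 (95% interval 0.37 to 0.86, exact McNemar test, two-sided, p = 0.0088). Summits had more G and C than flanks, with a mean of 49.5% (SD 7.67, n = 1925) against 35.9% (SD 8.71, n = 1925), and 87.1% of summits exceeded their own flank. Against 19240 genomic positions with the same G and C count, a control added after the data were seen, the ratio was 2.24 (95% interval 1.56 to 3.29, Fisher's exact test, p = 1.1e-04). With those positions drawn outside exons it was 2.07 (95% interval 1.45 to 3.04, Fisher's exact test, p = 3.4e-04). The ratio to the flanks was 0.76 in the list of replicate 2 alone (exact McNemar p = 0.23) and 0.66 without peaks near small RNA genes (exact McNemar p = 0.078).

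Other sequences marked the summits more often. GAGAGA lay at 480 summits (24.9%) and in 138 flanks (7.17%), a ratio of 3.48 (exact McNemar adjusted p = 3.8e-53). GGGCGG lay at 183 and 26 (ratio 7.04, exact McNemar adjusted p = 4.0e-31), CAAGTG at 111 and 62 (1.79, exact adjusted p = 3.8e-04) and CAGCTG at 74 and 37 (2.00, exact adjusted p = 8.0e-04). TGATAA, the GATA-factor site, was at 39 summits and 157 flanks (0.25, exact adjusted p = 6.7e-18), and TAATTA, a general homeodomain core, at 3.6% and 5.4% (0.67, exact adjusted p = 0.014). CACCTG and CACGTG did not pass against the flanks (exact adjusted p = 0.35 and 0.46). At the same G and C count both were lower, at 0.71 (Fisher's exact adjusted p = 0.011) and 0.62 (Fisher's exact adjusted p = 0.0038), and outside exons at 0.74 and 0.76 (Fisher's exact adjusted p = 0.032 and 0.12). Against positions of the same G and C count, the TAATTA ratio was 3.17 and the GAGAGA ratio 3.27, while those of CAAGTG and CAGCTG were 1.04 and 1.01. With such positions drawn outside exons these 4 ratios were 2.57, 2.40, 1.35 and 1.57. For GGGCGG the ratio was 1.76 at the same G and C count and 1.3 outside exons, and for TGATAA it was 0.47 and 0.55. Against the flanks, CAGCTG no longer passed in the list of replicate 2 alone (1.40, exact adjusted p = 0.18) or among the 962 strongest peaks (1.57, exact adjusted p = 0.17). Among those peaks CAAGTG did not pass either (1.54, exact adjusted p = 0.080), and TAATTA did not pass without peaks near small RNA genes (0.76, exact adjusted p = 0.13). Ranked by the difference between summits and flanks over the square root of their sum plus 1, CAATTAA was 7265th of 8192 7-mers and 24th of the 105 arrangements of its letters. In 5 groups of 385 peaks from strongest to weakest, CAATTAA lay at 1, 7, 5, 14 and 6 summits, with no steady trend. The strongest group differed from the weakest by -1.3 percentage points (permutation test, two-sided, p = 0.12). None of the 33 summits with CAATTAA was near a tRNA, snoRNA, snRNA or miRNA gene, and such genes take 24.9% and 14.8% of the strongest group. Within 100 bp of the summit the difference was -3.90 points (permutation p = 5.4e-04). With 3 groups in place of 5, CAATTAA lay within 50 bp of 6, 11 and 16 summits from strongest to weakest. That is a rise toward weaker peaks, with a difference of -1.56 points (permutation p = 0.0501).

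**Figure D4:**
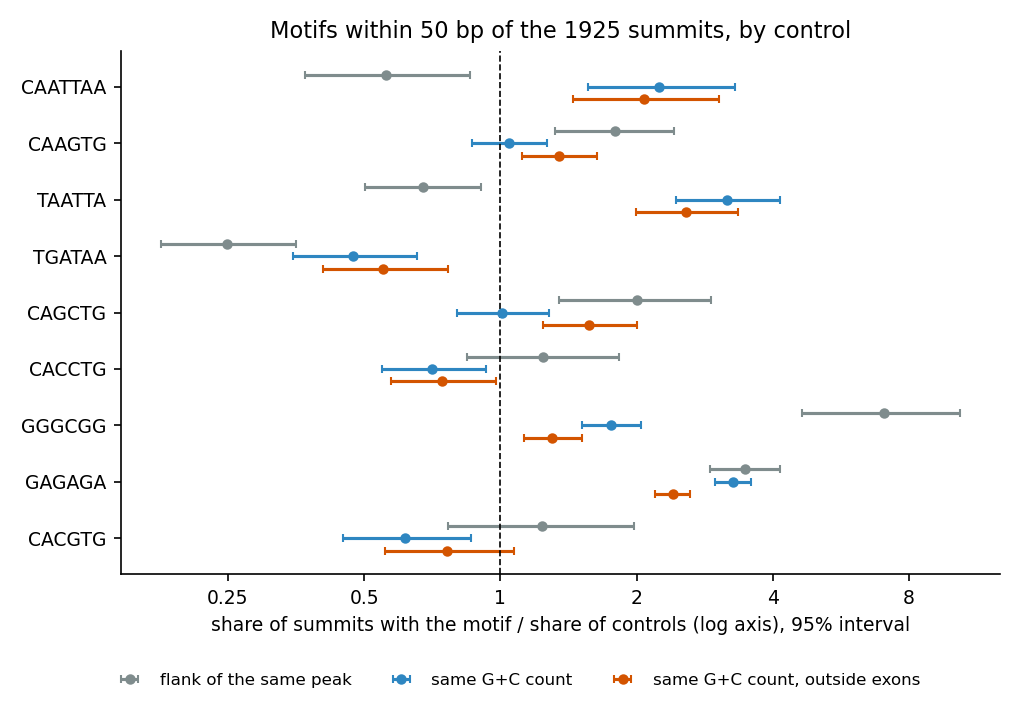
Ratio of the share of summits with each motif within 50 bp to the share of control windows (log axis, 95% intervals), for 3 controls: the flank of the same peak, positions of the same G and C count, and such positions outside exons. CAATTAA stands at 0.56 against flanks and at 2.24 and 2.07 against the other controls, and GAGAGA lies above 1 against all 3.

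The mls-2 gene itself carried a cluster of peaks. Within 20 kb of the gene (X 4758804–4761640, minus strand) lay 7 of the 1925 peaks, more than around 99.8% of protein-coding genes, for which the median was 0. The strongest, rank 41 with a signal of 1035, had its summit in an intron (X 4759745–4760087), and 2 more intronic peaks had signals of 399 and 329. The last of these (X 4759881–4760350) overlapped the strongest peak. A peak at the 5′ end (X 4761419–4761888, signal 343) had its summit 14 bp upstream, and the other 3 were intergenic, with signals of 334, 247 and 215. Only the peak at X 4752888–4753357 had CAATTAA within 50 bp of its summit. At unc-119 (III 10902641–10908935, plus strand), the other gene named in the strain's genotype, 1 peak lay within 20 kb (III 10922480–10922949, rank 1625, signal 231). Beyond 3 kb from the gene, the same 20 kb flanks held 12 regions of the pooled 30000-region list at mls-2 and 14 at unc-119, against a median of 8. The transgene adds copies of mls-2 sequence to the genome, and peaks on the native gene and on the transgene share 1 position here. Extra copies can raise the signal there, so a contribution of copy number to the cluster was not excluded.

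**Figure D5:**
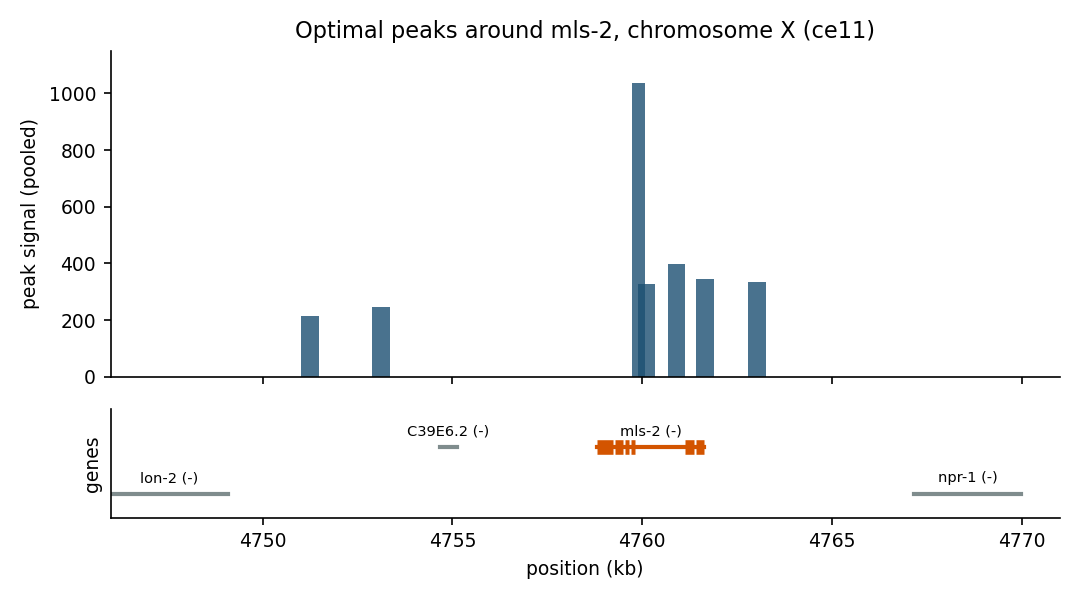
Peaks around mls-2 on chromosome X (upper panel, pooled signal against position in kb) above the protein-coding genes (lower panel, thick bars are mls-2 exons). The strongest peak, with a signal of 1035, lies in the largest intron of mls-2, and 7 peaks lie within 20 kb.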

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

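The list of replicate 2 held 10 regions on the mitochondrial genome, and that of replicate 1 and the pooled list held 0. They stood out because they lie outside the nuclear genome on which every comparison was made and the series held no control samples to set them against. The strongest of them was also the strongest region of that replicate's list, with a signal of 1245 against 977 for the strongest nuclear region, and 6 of its 20 strongest regions were mitochondrial. Leaving them out, a choice made after they were seen, left 63.4% of the peaks found in both replicates, the value with them. No optimal peak was mitochondrial, so this choice could not have lowered the share.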

How the results depend on the processing

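Of 310 alternatives to 44 results, 244 stayed on the same side of the test's threshold or, for values without a test, close to the value reported, 27 reversed direction, 16 were stronger, 15 weaker and 8 moved. No paired analysis was possible because the series holds 1 group of 2 replicates. The stricter list, of the strongest peaks, held 962. The share in both replicates was 70.2% for overlap, 51% at 50 bp, 94.0% against all regions and 71.5% in the stricter list. Matched on upstream length, 3 lists passed, and 2 in the stricter list. With 2000 bp upstream 7 lists passed, and with the nearest gene 11. A count of lists can stay while its members change, as without replicate 1, where the cell cycle list was lost and the pan-neuronal list gained. The list tied to mls-2 (ratio 1.36 to all genes) fell to 0 at 500 bp, in the stricter list and without replicate 1 (0–1.35 with 1 replicate left out), and was 1.95 at 2000 bp, 3.03 by nearest gene and 2.02 when matched on stretch length, none passing. The ratio for postembryonic mesoderm rose above 1 with the nearest gene (3.28, 1.88 when matched on stretch length), in the stricter list (1.62) and without replicate 1 (0.88–1.91 with 1 replicate left out). It fell below 1 for AWC (0), basic helix-loop-helix (0.81) and signalling genes (0) in the stricter list, for homeobox (0.93) and axon guidance genes (0.91) at 500 bp, and without a replicate for excretory (0.66–1.82), basic helix-loop-helix (0.48–1.32) and homeobox genes (0.86–1.68). For T-box, GATA, SOX and forkhead genes it was 1.49 with the nearest gene and 1.00 when matched, and for collagens 1.07 when matched. Cell cycle genes no longer passed at 500 bp (3.17), in the stricter list (1.08), without replicate 1 (2.54–5.86 with 1 replicate left out), matched on upstream length (3.39) or by nearest gene matched on stretch length (2.94). Histones no longer passed by nearest gene (1.46, matched 2.30). CAATTAA ranged from 0.39 to 0.76 without replicate 2 or 1, was 0.66 without peaks near small RNA genes, and reversed to 2.24 at the same G and C count and 2.07 outside exons. With the same 2 controls TAATTA reversed to 3.17 and 2.57, CACCTG to 0.71 and 0.74 and CACGTG to 0.62 and 0.76, and CACGTG was 0.97–1.28 with 1 replicate left out. The change of CAATTAA with signal was -3.90 points at 100 bp. Within 50 kb of unc-119 lay 3 peaks. Apart from the tests weighed in the closing observations, the causes of these changes were not tested. The G and C control shows that the direction depends on the control, not that base composition is the cause.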

Other observations

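The tests on gene families, on positions of the same G and C count, on nearest-gene lists matched on stretch length or without X, and those weighing the X density were chosen after the main results were seen. For X without tRNA genes, X among weaker regions and the lists matched on stretch length, the outcome that would count for or against the explanation was also set down after the values were seen. For the other weighed tests it was set down before, although for the lists without X the pooled value of the 8 lists had been seen. Another 3 tests were run and then left out of the weighing after their results were seen, to keep it to 3 patterns. The first compared tRNA genes with an identical copy (35.8% with a summit) and unique ones (21%). How reads shared between copies were handled is not given, so the direction of this difference decides nothing. The second took the tRNA excess in each replicate's own list (32.2-fold and 34.9-fold), and only for this one of the 3 was the outcome set down after the values were seen. The third counted pooled regions in the flanks of mls-2 (12 against a median of 8, with fewer at 66.5% of genes), which decided nothing.

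Beyond the fixed lists, promoter peaks gathered at several gene families. Among 175 families of genes that share a symbol prefix and have at least 10 members, 16 had a promoter summit more often than other genes and 5 less often (Fisher's exact test, Benjamini-Hochberg over the 175 families). The families were tested only with the 1000-bp window in the pooled list, and were not matched on upstream length. Besides the ribosomal protein genes, these included the hsp chaperones (7 of 22, exact adjusted p = 0.0043), with hsp-1 (IV 17278443–17278803, signal 680) and hsp-60 (III 1618976–1619270, signal 653), and the dnj co-chaperones (8 of 29, exact adjusted p = 0.0043), with dnj-29 (I 14113120–14113420, signal 807) and dnj-13 (II 11545362–11545611, signal 500). The eif translation initiation factors had a summit at 7 of 25 genes, with eif-3.C (I 9979753–9980056, signal 749), and the vps vesicle-sorting genes at 9 of 31. The mdt Mediator subunits had one at 6 of 20 genes and the cox cytochrome oxidase genes at 5 of 15, with cox-5B (I 9788578–9788855, signal 594). Prefixes given by mutant phenotype passed as well, among them lin (15 of 47, exact adjusted p = 1.3e-06) and unc (15 of 94, exact adjusted p = 0.0052). The peak shared by lin-35 and vps-51 counts for both lin and vps. The families below other genes were the chemoreceptor families str (1 of 193), srh (2 of 220), srw and srx (0 genes each), and the clec C-type lectin genes (3 of 240, exact adjusted p = 0.013).

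With each peak given to the nearest gene within 5000 bp, 1522 genes had a peak, and 11 of the 23 lists passed. Axon guidance and adhesion genes had a peak at 23 of 52, pan-neuronal synaptic genes at 12 of 31, Wnt, Notch, EGF and FGF pathway genes at 12 of 41 and neuronal terminal selectors at 11 of 41. Neuronal genes did not all go this way, with AWC genes at 4 of 25 (Fisher's exact adjusted p = 0.19), neuropeptides and insulins at 7 of 145 (0.63 times all genes) and chemoreceptors at 9 of 1310 (0.090 times). The strongest peaks of the axon guidance, pan-neuronal and pathway lists were at egl-17, an FGF gene (X 489758–490063, signal 923, within 200 bp of a tRNA gene), syd-2, the liprin-alpha gene (X 10555528–10555744, signal 575), unc-33 (IV 3521736–3522074, signal 481, intron) and cdh-9 (X 16590903–16591074, signal 427, within 200 bp of a tRNA gene).

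Of the lists that passed by nearest gene, 8 of developmental and neuronal genes had not passed with the 1000-bp window in the pooled list, and the room around such genes is a candidate explanation. Tested one by one among all 23 lists against random lists matched on the length of genome nearest to each gene, 3 of the 8 passed: axon guidance (ratio 2.53, permutation adjusted p = 0.0015), pan-neuronal synaptic genes (2.39, permutation adjusted p = 0.017) and the signalling pathways (2.44, permutation adjusted p = 0.023), below ribosomal proteins (3.93). Length stays open for the other 5, among them terminal selectors (1.97, permutation adjusted p = 0.11). The match was by decile of that length, so differences in length within a decile stay open for the 3 that passed as well. Without peaks and list members on X, 2 of the 8 passed, axon guidance (2.68, permutation adjusted p = 0.0031) and the pathways (2.68, permutation adjusted p = 0.032), and pan-neuronal genes did not (2.04, permutation adjusted p = 0.19), so that X stays open for them. Open chromatin was not tested, no biological explanation was tested, and a pooled test of the 8 lists was also run and is not used, since they were picked for passing.

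CAATTAA was rarer at summits than in the flanks, and the higher G and C content of summits could account for that direction. Against positions of the same G and C count the ratio was 2.24 (95% interval 1.56 to 3.29). The outcome set down for that explanation was an interval that reaches 1 or lies above it. The rarity was thus absent against such positions, though base composition alone would give a ratio near 1. Exon sequence among those positions was argued against as the source of the excess, since outside exons the ratio was 2.07 (95% interval 1.45 to 3.04), the highest of the 105 arrangements of the same letters, whose median was 0.92. Among the 801 summits outside promoter windows and small RNA genes the ratio was 1.95 (95% interval 1.18 to 3.37), with the motif at 16 of them. These values leave open whether a few peaks may hold homeodomain sites, and whether such sites would be of the HMX kind was not tested, TAATTA also being above 1 under both controls (3.17 and 2.57). CAATTAA was the only sequence of the panel fixed as an HMX site, so these values do not cover other sites the family may bind.

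Peaks were denser on X, and 3 technical explanations were tested. tRNA genes on X were argued against as the whole explanation, since without summits near tRNA genes the X ratio was 1.32 (95% interval 1.21 to 1.44). With those summits it was 1.43, and 42.9% of them lay on X, so a partial contribution stays open. Genes annotated as other noncoding RNA were not weighed, although 2520 of 7764 lie on X and 500 summits lay near such genes. The base composition of X was argued against, since 16.4% of genome positions with the summits' G and C counts lie on X, below the observed interval of 23.3% to 27.3%. A uniform lift of X over the control could not be decided. X held 15% of the 28075 pooled regions below the threshold (95% interval 14.6 to 15.4), under its 17.7% of the genome. That was the outcome set down against a lift, but those regions did not follow chromosome length elsewhere either. Chromosome III held 18.7% of them and 13.7% of the genome, and chromosome V 16.2% and 20.9%. A lift of X from a lower share would therefore go unseen. The density may be a property of the stronger peaks themselves, as a hypothesis, and no biological explanation was tested, the design having 1 group.

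By the difference between summits and flanks over the square root of their sum plus 1, the first 7-mers were CTCTCTC (220 summits, 39 flanks), GAGACGC (174 and 26) and GAGAGAC (156 and 19). GGTTCGA, which matches the internal promoter element of tRNA genes, was at 110 summits and 10 flanks.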
